A study of Mus musculus with 20 samples.

How the data were processed

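Liver RNA of 20 female mice had been hybridised to Illumina Mouse WG-6 v2.0 BeadChips, 1 array per mouse and 5 mice in each of 4 groups, per the labels. The groups were wild-type C57BL/6 (B6) mice and B6 mice homozygous for the kd missense allele of Pdss2, a gene needed to make coenzyme Q (CoQ); the mutants were untreated, fed probucol or given CoQ10. Groups were taken from the labels' treatment and source fields. For 10 of the 20 samples these fields and the array name in the description disagree: livers whose treatment field says probucol carry a prefix for untreated in the array name, and the reverse. The treatment field was kept for all results, and counts with these 2 groups exchanged are given among the alternatives. Urine albumin, given in the same label records, differs between these groups by the treatment field, with 0.84 to 1.86 mg per 24 h under probucol and 13.52 to 57.34 without treatment. These values do not tell which array holds which liver. Which field is right for the arrays was not settled here, so every direction between untreated and probucol-fed mutants, and every statement on either group, holds for livers as labelled in the treatment field.

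The deposited table held a linear bead intensity per probe and array, neither background-subtracted nor normalised between arrays, judged from the values and the file headers. Beside each intensity the authors deposited a detection value as a fraction from 0 to 1. It is headed as a p but rises with intensity (rank correlation between 0.99 and 0.996 over the arrays), so 1 minus this fraction was used as the detection p. A second deposited table held the authors' normalised log2 values of the same arrays, whose column medians lay between 7.81 and 7.82. Each of its 20 columns correlated best with the intensity column of its own sample. How those log2 values were normalised, and which scanner software was used, is not given in the sources used here. Their scale was taken as log2 and they were not centred by probe.

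Intensities were background-corrected by normexp with negative-control parameters inferred from the detection p (limma 3.58.1 in R 4.3.3, offset 16), quantile-normalised and log2-transformed. A probe was kept if its detection p was under 0.05 in at least 5 of 20 arrays, which left 15096 of 45281 probes. Probes were named from the platform annotation supplied with the series. It gave 1 symbol for 34885 probes, several for 18 and none for 10378, and 34807 of the named probes matched a gene of the GRCm38.p6 gene table through their gene identifier, which changed 0 symbols. Among kept probes 13202 had 1 symbol, 5 several and 1889 none. No probe was named Pdss2, so its own transcript was not analysed here. Genomic coordinates were not used. The gene table served only for names and for the order of genes along a chromosome.

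One linear model with 4 group means was fitted to all 20 arrays with limma (lmFit and eBayes), so that groups shared 1 estimate of the spread. Adjusted p values are Benjamini-Hochberg values within a comparison, called below 0.05, and the 6 comparisons cover all pairs of groups. Log2 differences are given with the standard error of the fit, and group sizes are 5 throughout. A probe detected in 0 of 5 livers of a group has only a bound there. Its fold is written as at least N-fold, the mean of the brighter group against the mean, over arrays, of the higher of the lowest detected signal and the probe's own value.

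For gene lists, 36 lists fixed beforehand were tested with limma's camera at a preset inter-gene correlation of 0.01, on the kept probe of highest mean for each gene (34 lists kept 3 or more genes), with Benjamini-Hochberg adjustment over lists. The test was repeated with the correlation estimated from the data. Members were counted as called over all probes and adjusted over the list alone. Genes named in the text followed a rule. For untreated mutants against wild type and for each treatment against untreated mutants, up to 12 rises and 12 falls of largest size were taken among named probes with adjusted p under 0.05 and groups that did not overlap. For the other 3 comparisons up to 4 and 4 were taken, and from described lists up to 4 members of smallest p. Genes outside this rule are marked where they appear. The groups, the tests of probes, lists and labels, the rule and the alternatives were fixed before the data were examined. Exceptions are the livers left out for standing apart and the tests marked as later under other observations.

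Urine albumin and the glomerular nephritis score were taken from the labels and compared by exact two-sided permutation tests. The number in the array name, 1 to 4, may stand for the slide, which the labels do not say. Each number was carried by 5 arrays and by all 4 groups, so values are given with it as a block and within each number. The numbers were not balanced, as wild type carried number 1 repeatedly, untreated mutants 2, probucol 3 and CoQ10 4. Number and group are therefore partly confounded in the fit without the block. The first principal component (24.2% of the variance) ran from -13.6 to 38.1 in arrays numbered 1 or 2. It ran from -25.8 to 2.24 in those numbered 3 or 4. Deviations from the group means correlated at a mean of 0.18 between mice of different groups with the same number and -0.0556 with different numbers, and 7 of 20 mice correlated best with their own number. Alternatives covered background correction, scaling, the authors' log2 values, the filter on dim probes, the variance model, array weights, 2-group fits, both blocks, the ages of untreated mutants and each mouse left out. Leaving out 2 untreated livers and 3 labelled probucol that stood apart was added after the data were seen.

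The fits were tested on simulated data, 20 simulations per comparison on 15096 probes with 200 changed probes, made by reassigning whole-array residuals. For untreated mutants against wild type, 23.4% of probes changed by 0.5 on the log2 scale, 84.4% of those changed by 1 and 99.0% of those changed by 2 were recovered, and 5.62% of calls were false. With nothing changed, a median of 0 probes was called in that comparison. The highest number called with nothing changed was 131, between the treatments. Camera at the preset correlation still called a mean of 5 of 36 lists for untreated mutants against wild type with nothing changed, and 0 with the estimated correlation. Arrays detected between 12268 and 15003 probes (detection p under 0.05). Correlations between arrays lay between 0.956 and 0.992 and showed no array deposited repeatedly. The number of arrays limits the precision.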

Results

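The data were liver expression profiles of 20 female mice, 5 in each of 4 groups. They addressed how a missense genotype of Pdss2, and lifelong feeding of probucol (a lipid-lowering antioxidant drug, about 95 mg per kg per day) or CoQ10 (about 400 mg per kg per day), relate to gene expression in the liver. Wild-type mice were 215 to 217 days old, untreated mutants 129 to 143, mutants labelled probucol 140 to 145 and mutants labelled CoQ10 153 to 156 days. The design therefore does not separate genotype from age in any comparison with wild type. Only the clustering of called genes along the chromosome of Pdss2, given under other observations, speaks against age alone, and only for those genes. Mutants labelled CoQ10 were also older than every mouse of the other mutant groups. Treatment and age are therefore not separated where CoQ10 is compared with untreated mutants or with probucol. Arrays detected a median of 13495 probes, and medians by group ran from 13286 to 14226. By the number in the array name, which each group spans, the medians were 12519, 12910, 14414 and 13967.

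Kidney disease, as recorded in the labels, separated the groups. Untreated mutants excreted 33.9 ± 20.3 mg of albumin per 24 h (SD, n = 5), wild-type mice 0.164 ± 0.023 and mutants labelled probucol 1.43 ± 0.38. By exact permutation, untreated mutants differed from wild type (adjusted p = 0.00794), and mutants labelled probucol lay below untreated mutants and above wild type (adjusted p = 0.00794 in each), which is the smallest p that 5 against 5 mice can give. No albumin values were given for CoQ10. The glomerular nephritis score averaged 2.8 ± 0.84 in untreated mutants and 0.2 ± 0.45 in wild type (exact permutation, adjusted p = 0.0476). It averaged 0.8 ± 1.3 under probucol and 0.8 ± 1.1 under CoQ10 (SD, n = 5 each), and neither differed from untreated mutants after adjustment (exact permutation, adjusted p = 0.0952).

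**Figure D1:**
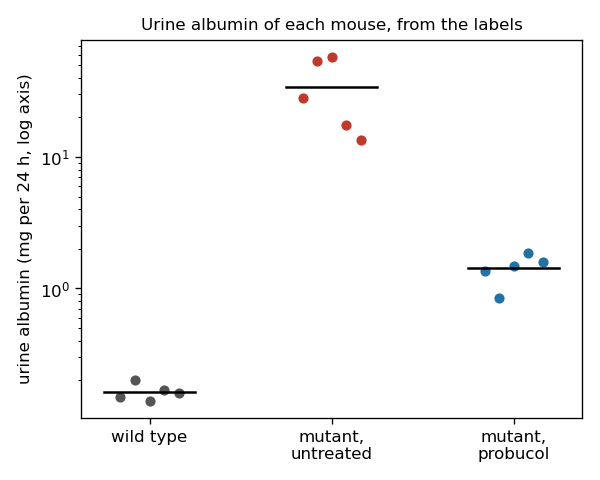
Urine albumin in mg per 24 h on a log axis, 1 point per mouse and a bar at the mean, for the 3 groups with values. Untreated mutants lie between 13.52 and 57.34, above mutants labelled probucol (0.84 to 1.86) and wild type (0.14 to 0.2).

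Untreated mutant livers differed from wild type in a small set of genes. Sult3a1, a sulfotransferase and a member of the female-biased list, was 6.51-fold higher (log2 2.70 ± 0.40, detected in 4 of 5 wild-type livers), and Cyp4a12a, a fatty acid hydroxylase of male liver, was at least 2.50-fold higher, detected in 5 of 5 mutant and 0 of 5 wild-type livers. Nudt7, a peroxisomal coenzyme A hydrolase, was 2.28-fold higher. Ddo, which encodes D-aspartate oxidase, was at least 2.22-fold lower in mutants, Rsph4a, a component of the radial spokes of cilia, at least 1.43-fold and Rev3l, the catalytic subunit of DNA polymerase zeta, at least 1.86-fold. G0s2, an inhibitor of triglyceride lipase, was 3.43-fold lower and Abcc4, an efflux transporter, 2.05-fold lower. In limma's fit the adjusted p was 3.10e-08 for Ddo, 1.24e-06 for Rsph4a, 2.89e-04 for Cyp4a12a and 0.00158 for Sult3a1. Sult3a1, Ddo, Rsph4a and Rev3l lie within 100 protein-coding genes of Pdss2, as described under other observations.

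In all, 18 of 15096 probes were called between untreated mutants and wild type, 5 higher and 13 lower, and they named 15 genes. An unadjusted p under 0.05 was reached by 831 probes, where chance alone gives 754.8. The remaining named rise was Gtf3c6, a subunit of a factor for RNA polymerase III (log2 0.65 ± 0.12). The remaining falls were Plekhb1 (-1.43 ± 0.20), Cd207, also called langerin (-1.03 ± 0.18), the mitochondrial carrier Slc25a34 (-1.02 ± 0.19, detected in 3 of 5 mutant livers), Zbtb24 (-0.97 ± 0.17), the splicing factor Cdc40 (-0.90 ± 0.12) and Ide, the insulin-degrading enzyme (-0.89 ± 0.12). All 18 probes had groups that did not overlap, as had 1.56% of all probes against 0.794% by chance. Without overlap a direction cannot change within an array number, so that all 18 kept theirs within all 4 tests nothing. With the array number as a block 25 probes were called. Probes of the same gene disagreed for Ddo (4 kept probes, from at least 2.22-fold lower to a log2 difference of 0.65), Ide (3 probes, -0.90 to 0.19) and Gtf3c6 (2 probes, 0.0043 to 0.65), and Cyp4a12a and Sult3a1 belong to families of similar sequence whose members a probe may share. Calls of Gtf3c6, G0s2, Cd207, Slc25a34 and Zbtb24 depended on single mice. G0s2 was not called without wild-type replicate 2, 4 or 5 or untreated replicate 1, 4 or 5 (adjusted p = 0.0568 to 0.0805), Slc25a34 without wild-type replicate 3 or 4 or untreated replicate 1, 2 or 3 (0.0533 to 0.0818) and Gtf3c6 without wild-type replicate 3, 4 or 5 (0.0568 to 0.0643). Cd207 was not called without wild-type replicate 2 or 4 or untreated replicate 1, and Zbtb24 without wild-type replicate 2 or untreated replicate 1 (0.0588 to 0.0707 for each). Without background correction dim genes differed less (log2 1.57 for Sult3a1, -0.48 for Abcc4, -0.50 for Cd207 and Cdc40, -0.52 for Zbtb24 and -0.38 for Slc25a34), and Gtf3c6 was not called (adjusted p = 0.0601). The authors' log2 values lost Gtf3c6 and Cd207 (0.0791 to 0.172), no filter lost G0s2 and Slc25a34 (0.0551 to 0.0856), and leaving out the 2 youngest untreated mutants lost Gtf3c6, G0s2, Cd207 and Zbtb24 (0.135 to 0.197). Median scaling called 9 probes, 4 higher and 5 lower, without these 5 genes, Abcc4, Cdc40 and Ide (0.121 or more), and naming the groups by the array name prefix turned the count into 106, 43 higher and 63 lower.

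**Figure D2:**
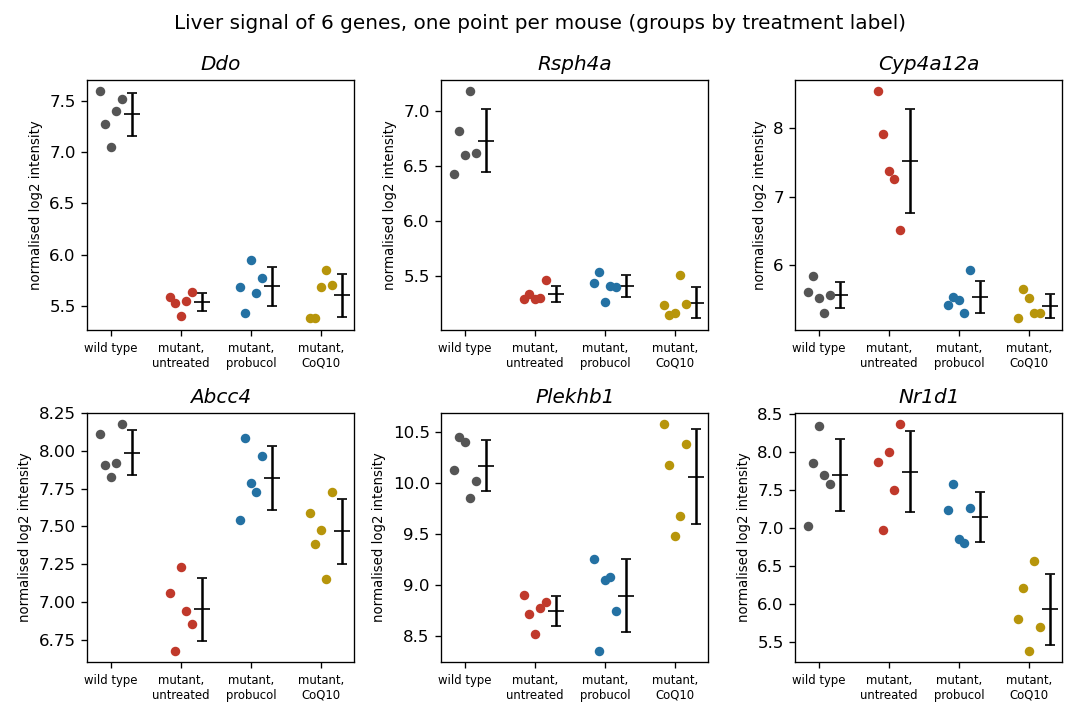
Normalised log2 intensity of 6 genes, 1 point per mouse with the group mean and SD beside it, groups by the treatment label. Ddo and Rsph4a were detected in 5 of 5 wild-type livers and in 0 of 5 livers of untreated mutants, and Cyp4a12a the other way round.

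Most members of 3 metabolic gene groups lay to the same side of wild type in untreated mutants, at small sizes, and none of these 3 was called with an estimated correlation. All 31 measured genes of the PPAR alpha and fatty acid oxidation list lay lower in mutants (median -0.25), among them Pdk4 (-1.38 ± 0.41), a kinase that inhibits pyruvate dehydrogenase, and the thioesterase Acot4 (-0.58 ± 0.18). Complexes II to V of oxidative phosphorylation lay higher in 30 of 33 genes (median 0.17), such as Cox7b (0.52 ± 0.16) and Uqcr11 (0.44 ± 0.13). Complex I lay higher in 32 of 34 (median 0.17), such as Ndufb2 (0.67 ± 0.23) and Ndufa2 (0.31 ± 0.13). Replicates 1 and 4 of the untreated mutants stood apart, at -14.9 and -12.7 on the second principal component against 7.05 to 17.3 in the other 3, and for Ndufb2 at 10.46 and 10.59 against at most 9.51 (wild type at most 9.40). With these 2 livers left out, a choice made after seeing the data, complex I was not called (median 0.07, adjusted p = 0.0902), and complexes II to V had a median of 0.12 (adjusted p = 0.00178). The genes Nudt7, Gtf3c6, G0s2, Cd207, Slc25a34 and Zbtb24 also lost their calls then (0.0935 to 0.317), and the medians of Kupffer markers and fatty acid synthesis, described below, were 0.15 and 0.30, both called. No gene of these 3 lists was called alone, over all probes or adjusted over the list alone. Camera at the preset correlation called the 3 lists with adjusted p of 5.71e-09, 9.22e-09 and 8.59e-08. With an estimated correlation the adjusted p was 0.246, 0.176 and 0.304. Over all lists 8 of 36 were called at the preset correlation, where simulated livers with nothing changed gave a mean of 5.

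Male-biased liver genes lay higher in untreated mutants, 10 of 14 with a median of 0.55, of which 1 was called over all probes and 5 adjusted over the list alone. Beside Cyp4a12a, Nudt7 at its brightest probe differed by 0.97 ± 0.20. Markers of Kupffer cells and macrophages lay higher in 15 of 17 genes (median 0.27), with Folr2 (0.53 ± 0.15) and C1qc (0.27 ± 0.10) of smallest p and 1 called adjusted over the list alone. Camera gave adjusted p of 6.87e-07 and 1.69e-05 for these lists, and adjusted p = 0.115 and 0.226 with an estimated correlation. The 2 measured cholangiocyte markers, Sox9 (-0.95 ± 0.25) and Krt23 (-1.02 ± 0.32), were lower, both called adjusted over the list alone and neither over all probes. This was the 1 list of 36 still called with an estimated correlation (adjusted p = 0.0236). Fatty acid and triglyceride synthesis lay higher (13 of 18, median 0.18, with Thrsp at 0.85 ± 0.34 and Srebf1 at 0.46 ± 0.19), and Nrf2 targets lower (13 of 23, median -0.10, with Akr1b8 at least 1.29-fold lower, detected in 0 of 5 mutant livers, and Gstm1 at -0.40 ± 0.12, both called adjusted over the list alone). Their adjusted p of 0.0386 and 0.0257 became adjusted p = 0.375 and 0.331 with an estimated correlation, and adjusted p = 0.102 for both with the array number as a block. The synthesis list was not called without wild-type replicate 1 or 4 or untreated replicate 3 or 5 (adjusted p = 0.147 to 0.225), nor Nrf2 targets without wild-type replicate 2 or 3 or untreated replicate 2 or 5 (0.0548 to 0.209). The synthesis list was also lost with no filter and in a fit of 2 groups (0.0523 to 0.0585), and Nrf2 targets under median scaling, with the authors' log2 values, with detection in all 20 arrays and without the 2 youngest mutants (0.0536 to 0.0963). Cholangiocyte markers were not called with no filter (median -0.13, adjusted p = 0.0564). With 1 mouse left out the median ran from -0.39 to -0.14 for fatty acid oxidation, fell to 0.11 for the synthesis list and to -0.0059 for Nrf2 targets, which lay at -0.05 with the array number as a block, and for male-biased genes it fell to 0.20 with no filter. In the blocked fit the medians were -0.29 for fatty acid oxidation, 0.17 for both respiratory lists, 0.51 for male-biased genes, 0.27 for Kupffer markers and -0.97 for cholangiocyte markers. Within array numbers the median ranged from -0.67 to 0.03 for fatty acid oxidation, from -0.06 to 0.34 for complex I, from 0.0068 to 0.33 for the other complexes and from 0.10 to 0.73 for male-biased genes. It ranged from -0.09 to 0.60 for Kupffer markers and from -1.17 to -0.68 for cholangiocyte markers. The other 28 lists were not called.

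Livers labelled probucol differed from untreated mutants in 2 genes. Cyp4a12a was at least 2.52-fold lower, detected in 0 of 5 livers labelled probucol and 5 of 5 labelled untreated (limma, adjusted p = 9.01e-04). Abcc4, an efflux transporter, was 1.83-fold higher (log2 0.87 ± 0.13, adjusted p = 0.0136). Both genes had differed from wild type in the opposite direction in untreated mutants, whose shared livers by themselves favour opposite signs. These directions hold only if the treatment field, not the array name prefix, is right. Of 15096 probes these were the 2 called, 1 higher and 1 lower, with 926 at an unadjusted p under 0.05. Cyp4a12a lay lower within all 4 array numbers, and Abcc4 differed by 0.48 to 1.13 within them. As the groups did not overlap for either gene, the directions within numbers were fixed beforehand. With the array number as a block 1 probe was called, Cyp4a12a, and Abcc4 was lost (log2 0.88, adjusted p = 0.0532), and in limma's fit of these 2 groups alone 0 were (adjusted p = 0.203 for Cyp4a12a and 0.268 for Abcc4). Abcc4 was also lost under median scaling (0.559) and without the 2 youngest untreated mutants (0.126) or replicates 1 and 4 (0.135), and without background correction it differed by 0.39. Abcc4 was not called without probucol replicate 2 or untreated replicate 2 or 4 (adjusted p = 0.0501 to 0.0528). The count was 1 without probucol replicate 2 or untreated replicate 4, 4 without untreated replicate 3 or 5, and 7 without probucol replicate 5.

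Between livers labelled probucol and untreated mutants 7 gene lists were called at the preset correlation, at small sizes, and 0 with an estimated correlation. The acute phase list lay higher in 19 of 25 genes (median 0.23), with the chemokine gene Cxcl1 at 1.84 ± 0.47 and Apcs, serum amyloid P, at 0.99 ± 0.26, and 3 genes called adjusted over the list alone. Endoplasmic reticulum chaperones lay higher in 13 of 15 (median 0.26), with Sdf2l1 at 0.71 ± 0.29 and Sel1l at 0.28 ± 0.13, and cell cycle genes in 9 of 11 (median 0.29), with Mcm4 at 0.54 ± 0.19. Fatty acid oxidation lay lower in 24 of 31 genes (median -0.19), with Acot1 at -1.19 ± 0.38, and gluconeogenesis and amino acid catabolism in 15 of 17 (median -0.18), with Creb3l3 at -0.44 ± 0.15. Male-biased genes lay lower in 9 of 14 (median -0.22), with Cyp4a12b at least 1.37-fold lower, detected in 0 of 5 livers labelled probucol, while Serpina1e was higher (2.09 ± 0.74, called adjusted over the list alone), and stellate cell and matrix markers in 10 of 11 (median -0.21), with Reln at -0.49 ± 0.14. Over all probes only Cyp4a12a among the members of these 7 lists was called. Camera at the preset correlation called the 7 with adjusted p from 5.29e-05 to 0.00322. With an estimated correlation their adjusted p ran from 0.0655 for matrix markers to 0.616 for fatty acid oxidation. Simulated livers with nothing changed gave a mean of 4.3 called lists in this comparison, against these 7. Without probucol replicate 2 neither fatty acid oxidation nor cell cycle genes were called (the former also not without untreated replicate 3, adjusted p = 0.151 to 0.21, and the latter at 0.228), nor were male-biased genes without probucol replicate 3 (0.0505) or with detection in all 20 arrays (0.491). Without the 2 youngest untreated mutants fatty acid oxidation, gluconeogenesis, cell cycle genes and matrix markers were not called (0.0596 to 0.176). Under alternatives medians were as small as 0.11 for acute phase, 0.15 for cell cycle, -0.11 for fatty acid oxidation, gluconeogenesis and matrix lists and -0.0026 for male-biased genes, and reached 0.46 for chaperones. The gluconeogenesis median was larger, at -0.26, without the 2 youngest untreated mutants. Probucol replicates 1, 2 and 4 stood apart from replicates 3 and 5 (Apcs 12.09 to 12.53 against 10.93 and 11.23). Apcs is itself in the acute phase list, so a smaller median of that list without these livers was built in. On the second principal component replicate 3 (-12.2) did not stand apart from them, lying between replicate 2 (-4.51) and replicate 1 (-17.8). With those 3 left out, which leaves 2 livers, 0 probes and 1 list were called, and medians were 0.03 for acute phase, 0.04 for fatty acid oxidation, -0.05 for chaperones and -0.19 for cell cycle genes (adjusted p = 0.527 to 0.923), while male-biased genes were still called (-0.47). Within array numbers the median of the acute phase list ran from -0.02 to 0.65, that of cell cycle genes from -0.20 to 1.19 and that of matrix markers from -0.37 to -0.0021. With the array number as a block these medians were 0.22, 0.34 and -0.22.

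Livers labelled CoQ10 differed from untreated mutants in 12 named genes. Nr1d1, which encodes the circadian repressor REV-ERB alpha, was 3.52-fold lower (log2 -1.82 ± 0.26) and Enpp6 3.22-fold lower, each detected in 1 of 5 of those livers, and Ppargc1a, a coactivator of mitochondrial and gluconeogenic genes, 2.14-fold lower. Cyp4a12a was at least 2.53-fold lower, detected in 0 of 5 livers labelled CoQ10. Plekhb1 was 2.48-fold higher (1.31 ± 0.20) and Erdr1 2.02-fold higher. Adjusted p values from limma were 3.09e-04 for Cyp4a12a, 8.01e-04 for Enpp6, 0.00247 for Nr1d1, 0.00311 for Plekhb1 and 0.0418 for Ppargc1a. Without background correction the log2 difference was as small as -0.71 for Nr1d1, -0.62 for Enpp6 and -0.78 for Csrnp1, all still called, and -0.65 for Ppargc1a.

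This comparison called 18 probes, 7 higher and 11 lower, naming 12 genes, with 1415 at an unadjusted p under 0.05. Further falls were Arrdc2, at least 1.92-fold, and Csrnp1 (-1.29 ± 0.17), Spata2l (-1.23 ± 0.21) and Mast3 (-1.08 ± 0.21). The other named rises, Cmpk2 (1.00 ± 0.20) and Itgae (0.81 ± 0.16, detected in 1 of 5 untreated mutants), had overlapping groups and are named after their values were seen, and the 3 kept probes of Itgae ran from -0.03 to 0.81. Of the 18, 15 did not overlap, which fixes their direction within each array number. All 18, those with overlap included, kept their direction within all 4 array numbers. In the fit with the array number as a block 14 probes were called, and Ppargc1a and Mast3 were no longer among them (adjusted p = 0.0713 for both). Arrdc2, Ppargc1a and Mast3 were also lost without background correction (0.0571 to 0.0656) and with the authors' log2 values (0.0549 to 0.0805). These 3 and Erdr1 were lost with no filter (0.0971 to 0.149), and these 4 and Spata2l in a fit of 2 groups (0.0686 to 0.102), without the 2 youngest untreated mutants (0.23 to 0.317) and, with Csrnp1, under median scaling (0.0749 to 0.37). Without untreated replicates 1 and 4, which stood apart, 60 probes were called, 41 higher and 19 lower, and not Erdr1, Arrdc2, Spata2l or Ppargc1a (0.0505 to 0.079). Arrdc2 and Ppargc1a were not called without any single CoQ10 replicate, untreated replicate 1, 3, 4 or 5, wild-type replicate 2, 4 or 5 or probucol replicate 1 or 4 (adjusted p = 0.0512 to 0.126). Mast3 was lost for the same mice except probucol replicate 4 (0.05 to 0.122), Erdr1 without untreated replicate 1, 4 or 5 or CoQ10 replicate 2, 3 or 5 (0.0631 to 0.106), and Spata2l without untreated replicate 4 or 5 (0.05 to 0.0564). The count was 11 without untreated replicate 1, 4 or 5, 37 without untreated replicate 2, 28 without probucol replicate 3 and 7 under median scaling, 2 higher and 5 lower. Naming groups by array name prefix gave 7.

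Clock genes lay lower in 10 of 14 list members in livers labelled CoQ10 (median -0.70), with 1 lower over all probes, and 7 lower and 1 higher adjusted over the list alone. The higher gene was Arntl, an activator of the clock (1.45 ± 0.30). Interferon response genes lay higher in 19 of 21 (median 0.24), with Ifi27 at 0.73 ± 0.17 called adjusted over the list alone and Isg15 at 0.94 ± 0.32. Kupffer markers lay higher in 16 of 17 (median 0.20), with Folr2 at 0.51 ± 0.15 and C1qa at 0.49 ± 0.17. The integrated stress response list lay lower in 11 of 14 (median -0.19), with Trib3 at -1.50 ± 0.31 and Chac1 at -1.55 ± 0.46, both called adjusted over the list alone. Camera gave adjusted p of 2.66e-04 for clock and interferon genes, 0.00102 for Kupffer markers and 0.0148 for the stress response. With an estimated correlation the adjusted p was 0.225 for clock genes and the stress response, 0.408 for interferon and 0.406 for Kupffer markers. Simulated livers with nothing changed gave a mean of 5.85 called lists, against these 4. The stress response was not called without untreated replicate 4 or CoQ10 replicate 4 (adjusted p = 0.0519 to 0.0671), nor without the 2 youngest untreated mutants (0.138) or replicates 1 and 4 (0.09). Without background correction the medians were -0.35 for clock genes, 0.13 for interferon genes and -0.08 for the stress response. In the order clock, interferon, Kupffer and stress response, medians with the array number as a block were -0.73, 0.27, 0.20 and -0.19, and within array numbers they ran from -1.48 to -0.05, 0.09 to 0.64, -0.06 to 0.30 and -0.31 to -0.13.

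Livers labelled probucol differed from wild type in more genes. Serpina1e, of the alpha-1-antitrypsin family, was 9.46-fold higher, Cxcl1 5.81-fold and Apcs 2.63-fold. Krt23, detected in 4 of 5 livers labelled probucol, was 3.79-fold lower, the acyl-coenzyme A thioesterase Acot1 3.70-fold, G0s2 3.15-fold and Ddo at least 2.27-fold. The histone gene H2ac7 was 2.72-fold higher. Probucol replicates 1, 2 and 4 stood apart, with Serpina1e at 14.89 to 15.80 against 11.89 and 12.15 in replicates 3 and 5 (wild type at most 11.22) and Cxcl1 at 10.66 to 12.32 against 9.88 and 9.20. These 3 livers hold the highest values of both genes, so leaving them out was bound to lower these differences. With those 3 left out, chosen after seeing the data, the log2 difference was 1.25 for Serpina1e, 1.29 for Cxcl1, 0.65 for Apcs, 0.74 for H2ac7, -1.24 for Acot1, -0.74 for G0s2 and -1.97 for Krt23, none of them called (adjusted p = 0.172 to 0.782), and 13 probes were called, 2 higher and 11 lower. Without background correction H2ac7 differed by 0.73 and Krt23 by -0.91. Of 106 called probes 43 were higher and 63 lower, and 105 kept their direction in all 4 array numbers. For 94 of them this was fixed beforehand, as their groups did not overlap. A block for the array number gave 116 and lost the call of Serpina1e (log2 3.05, adjusted p = 0.0683). Fatty acid oxidation lay lower in 31 of 31 genes (median -0.49), 19 of them called adjusted over the list alone and 1, Acot1, over all probes (camera, adjusted p = 1.69e-13). With an estimated correlation the adjusted p was 0.253. Kupffer markers lay higher in 14 of 17 (median 0.22, camera adjusted p = 3.44e-04, and adjusted p = 0.284 with an estimated correlation), with 2 called adjusted over the list alone. Neutrophil and monocyte markers, of which 3 were measured, lay higher in 3 of 3 (median 1.00, camera adjusted p = 0.0174, and adjusted p = 0.284 with an estimated correlation), with S100a8 (1.36 ± 0.45) called adjusted over the list alone. They were not called without wild-type replicate 3 (0.0509) or with no filter (median 0.02, adjusted p = 0.182). The 2 cholangiocyte markers lay lower (Krt23 above, and Sox9 at -0.17 ± 0.25), with Krt23 called over all probes (camera adjusted p = 0.0189, and adjusted p = 0.253 with an estimated correlation). They were not called without probucol replicate 2 or 5 (0.0576 to 0.0879) or with detection in all 20 arrays (0.73). The other called lists had medians of 0.31 for acute phase genes, 0.36 for cell cycle genes, 0.26 for cholesterol synthesis, 0.20 for endoplasmic reticulum chaperones, 0.16 for complex I, 0.13 for complexes II to V, -0.29 for gluconeogenesis and amino acid catabolism, -0.20 for bile acid synthesis and transport and -0.19 for drug metabolism under CAR and PXR. Their camera adjusted p ran from 2.33e-05 to 0.0318, and adjusted p = 0.253 to 0.566 with an estimated correlation. Of these, with the 3 livers left out, acute phase, gluconeogenesis, cholesterol, bile acid, drug metabolism, neutrophil and cholangiocyte lists were not called (0.132 to 0.843), medians were -0.12 for chaperones and -0.09 for cell cycle genes, and that of fatty acid oxidation was -0.25 and still called. Under other alternatives medians were as small as 0.14 for acute phase, 0.20 for cell cycle, 0.17 for cholesterol, 0.08 for complexes II to V, -0.18 for gluconeogenesis, -0.08 for bile acid, -0.07 for drug metabolism and -0.17 for cholangiocyte lists, and as large as 0.35 for chaperones, 0.31 for complex I and 0.28 for complexes II to V. In all 13 lists were called, where nothing changed gave a mean of 4.55. With the array number as a block the medians of fatty acid oxidation, Kupffer and neutrophil lists were -0.52, 0.23 and 1.04, and chaperones were not called (adjusted p = 0.145). Within array numbers those medians ran from -0.79 to -0.08, 0.10 to 0.36 and -0.69 to 2.41, and that of cholangiocyte markers from -1.67 to -0.79. Chaperones, drug metabolism and bile acid genes also lost their calls without single mice (0.0511 to 0.252), the latter 2 also under median scaling (0.209 to 0.295). Drug metabolism was also lost with the authors' log2 values (0.0728) and with probes of a gene averaged (0.0564), and it and chaperones with detection in all 20 arrays (0.0856 to 0.109). The count moved to 27, 44, 44, 43, 60, 24 and 269 without wild-type replicates 2, 3 and 4 and probucol replicates 1, 2, 4 and 5, to 9 (2 higher, 7 lower) under median scaling, and to 18 with groups by array name prefix. Median scaling lost Serpina1e, H2ac7, Apcs, Acot1 and G0s2 (adjusted p = 0.0834 to 0.273), no filter Serpina1e, H2ac7, Acot1 and G0s2 (0.0616 to 0.135), a fit of 2 groups Serpina1e, Cxcl1, Acot1 and G0s2 (0.0511 to 0.0677) and the authors' log2 values Serpina1e (0.0567). Serpina1e and Acot1 have close family members. Serpina1e was not called without any single wild-type replicate, probucol replicate 1, 2 or 4, untreated replicate 5 or CoQ10 replicate 2 or 4 (adjusted p = 0.0508 to 0.161), H2ac7 without wild-type replicate 1, 2, 3 or 4 or probucol replicate 1, 2 or 4 (0.0562 to 0.105), G0s2 without wild-type replicate 2 or 4 or probucol replicate 1, 2 or 4 (0.0508 to 0.0739). Acot1 was lost without wild-type replicate 2 or 4 or probucol replicate 2 or 4 (0.0612 to 0.0932), and Cxcl1 and Apcs without wild-type replicate 2 or probucol replicate 4 (0.0521 to 0.0527).

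Livers labelled CoQ10 differed from wild type in 66 probes, which named 54 genes. Ifi27l2a, an interferon-induced gene, was 2.71-fold higher, Cox7a1 2.25-fold, Ndufb2 2.15-fold and Calhm6 2.07-fold. Enpp6 was 3.49-fold lower and Nr1d1 3.41-fold, each detected in 1 of 5 livers labelled CoQ10, and Ddo and Rsph4a at least 2.28-fold and 1.46-fold. Without background correction the log2 difference was -0.68 for Enpp6, -0.69 for Nr1d1, 0.64 for Cox7a1 and 0.46 for Calhm6. Kupffer markers lay higher in 16 of 17 genes (median 0.37), with Folr2 (1.04 ± 0.15) and C1qa (0.88 ± 0.17) called over all probes and 11 called adjusted over the list alone. Camera gave an adjusted p of 1.52e-09, and with an estimated correlation the adjusted p was 0.117. Clock genes lay lower in 10 of 14 (median -0.66, camera adjusted p = 0.00182, and adjusted p = 0.321 with an estimated correlation), 1 of them called over all probes, and 6 lower and 1 higher adjusted over the list alone. The other called lists had medians of 0.26 for interferon genes, 0.17 for complex I, 0.20 for complexes II to V, 0.13 for glycolysis, 0.27 for male-biased genes, -0.29 for fatty acid oxidation, -0.26 for endoplasmic reticulum chaperones and -0.12 for gluconeogenesis and amino acid catabolism. Their camera adjusted p ran from 1.60e-06 to 0.0259, and adjusted p = 0.321 to 0.53 with an estimated correlation. Glycolysis, male-biased genes, chaperones and gluconeogenesis lost their calls without single mice (0.0527 to 0.269), chaperones also with the authors' log2 values (0.0759) and gluconeogenesis under median scaling (0.0887). Under alternatives medians were as small as -0.37 for clock genes, -0.19 for fatty acid oxidation, -0.15 for chaperones and 0.07 for glycolysis, and ran from 0.14 to 0.42 for male-biased genes and from -0.22 to -0.07 for gluconeogenesis. The clock median was larger, at -0.997, without wild-type replicate 1. Of 36 lists 10 were called, where nothing changed gave a mean of 3.9. The Kupffer and clock medians were 0.40 and -0.75 with the array number as a block, and ran from 0.22 to 0.59 and from -1.63 to -0.18 within array numbers. Of 66 called probes 30 were higher and 36 lower, and 317 were called with the array number as a block, 193 higher and 124 lower. Under median scaling 9 were called, 1 higher and 8 lower, without Ifi27l2a, Cox7a1, Ndufb2 and Calhm6 (adjusted p = 0.12 to 0.504). No filter lost Cox7a1, Ndufb2 and Calhm6 (0.081 to 0.115), the authors' log2 values Cox7a1 and Calhm6 (0.0521 to 0.0765), and no background correction Calhm6 (0.0552). The count was 101, 22, 36, 24 and 38 without wild-type replicates 1 to 5 in turn, and 32, 31, 37 and 40 without CoQ10 replicates 1, 3, 4 and 5. Ifi27l2a was not called without wild-type replicate 2 (adjusted p = 0.052), C1qa without wild-type replicate 2 or 4 or CoQ10 replicate 1 (0.0595 to 0.0677), Ndufb2 without wild-type replicate 2, 3 or 4 or any single CoQ10 replicate (0.0501 to 0.0993). Cox7a1 was lost without wild-type replicate 1, 2, 4 or 5, CoQ10 replicate 1, 2, 3 or 4 or untreated replicate 3 (0.05 to 0.128), and Calhm6 without wild-type replicate 2, 3, 4 or 5, any single CoQ10 replicate, probucol replicate 2, 4 or 5 or untreated replicate 3 (0.0502 to 0.144).

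The treatments differed from each other in 7 probes, 5 higher and 2 lower in livers labelled probucol than in those labelled CoQ10. Cxcl1 was 9.26-fold higher (limma, adjusted p = 0.00664), Enpp6 2.48-fold (detected in 1 of 5 livers labelled CoQ10) and the phosphodiesterase gene Pde6c 2.33-fold (3 of 5), while Plekhb1 was 2.24-fold lower and Cyb5d2 1.73-fold lower (detected in 3 of 5 livers labelled probucol). Acute phase genes lay higher in 22 of 25 (median 0.27, camera adjusted p = 2.05e-08), with 1 called over all probes and 9 adjusted over the list alone. Endoplasmic reticulum chaperones lay higher in 15 of 15 (median 0.48, adjusted p = 2.43e-07), with 2 called adjusted over the list alone. With an estimated correlation the adjusted p was 0.126 and 0.31. Interferon response genes lay lower in 19 of 21 (median -0.23, camera adjusted p = 0.00101) and Kupffer markers in 15 of 17 (median -0.20, adjusted p = 0.00433), with 0 members called adjusted over the list alone. For both the adjusted p was 0.451 with an estimated correlation. The other called lists had medians of 0.25 for cholesterol synthesis, 0.22 for clock genes, -0.26 for matrix markers and -0.14 for fatty acid oxidation, with camera adjusted p from 0.00338 to 0.0241, and adjusted p = 0.109 to 0.651 with an estimated correlation. Cholesterol synthesis, clock genes and fatty acid oxidation lost their calls without single mice (0.0533 to 0.517), and the median of cholesterol synthesis was 0.03 without CoQ10 replicate 1 and 0.46 without CoQ10 replicate 3. Under alternatives other medians were as small as 0.31 for chaperones, 0.18 for acute phase, -0.10 for interferon, -0.08 for Kupffer, 0.12 for clock, -0.09 for matrix and -0.04 for fatty acid oxidation lists, and as large as 0.34 for clock genes and -0.21 for fatty acid oxidation. Clock genes were also lost without background correction (0.0638), both clock genes and cholesterol synthesis with the authors' log2 values (0.0568 to 0.102), and clock genes and fatty acid oxidation with detection in all 20 arrays (0.0624 to 0.184). In all 8 lists were called where nothing changed gave a mean of 5.75. In the order acute phase, chaperones, interferon and Kupffer, medians within array numbers ran from 0.14 to 0.61, -0.12 to 0.98, -0.28 to -0.25 and -0.30 to -0.10, and they were 0.27, 0.48, -0.24 and -0.20 with the array number as a block. A limma fit of these 2 groups alone called 0 probes (adjusted p = 0.0953 to 0.203 for the 5 genes), against 1503 at an unadjusted p under 0.05 in the shared fit. The count was 2, 65 and 26 without probucol replicates 2, 3 and 5, and 3, 2, 4 and 17 without CoQ10 replicates 1, 2, 3 and 4. With probucol replicates 1, 2 and 4 left out 0 probes were called (Cxcl1 at 1.97, adjusted p = 0.351 to 0.664 for the 5 genes), the acute phase median was 0.07 and still called, and chaperones (median 0.14), Kupffer markers, matrix markers, clock, cholesterol and fatty acid oxidation genes were not called (0.0566 to 0.604). Without background correction Pde6c differed by 0.45, and Enpp6 (0.46) and Cyb5d2 (-0.28) were lost (adjusted p = 0.0562 to 0.0595) as they were with the authors' log2 values (0.0615 to 0.146), Plekhb1 and Cyb5d2 with array weights (0.0614 to 0.0908), all named genes but Pde6c with no filter (0.0618 to 0.0686), and Pde6c, Plekhb1 and Cyb5d2 under median scaling (0.118 or more). Median scaling gave 2, both higher, the block for the array number 7, and groups by array name prefix 18. Cyb5d2 was not called without wild-type replicate 2, 3 or 4, probucol replicate 1 or 2, untreated replicate 1, 2, 3 or 5 or CoQ10 replicate 1, 2, 3 or 5 (adjusted p = 0.0506 to 0.118), Enpp6 without probucol replicate 2 or CoQ10 replicate 2, 3 or 5 (0.0593 to 0.0903) and Plekhb1 without probucol replicate 2 or CoQ10 replicate 1, 2 or 5 (0.0614 to 0.0903).

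Genes called in all 3 mutant groups against wild type were Ddo, Rsph4a, Rev3l, Cdc40, Zbtb24, Ide and Slc25a34, all lower, and Gtf3c6, higher. Other kept probes of Ide, Ddo and Gtf3c6 did not all move the same way. In livers labelled probucol and CoQ10, probes of Ide reached log2 differences of 0.47 and 0.73 from wild type, and those of Ddo 0.38 and 0.48. The other probe of Gtf3c6 differed by 0.03 and -0.20. The genes called in all 3 mutant groups make 8 probes. The wild-type livers are shared by the 3 comparisons, and 50 simulations of unchanged groups gave 0 such probes. With nothing changed, 20 other simulations called at most 0, 0 and 1 probes in the 3 comparisons, so there is almost nothing to share and the 0 does not show how many the shared livers give. Untreated and probucol mutants shared 11 called probes with the same direction, untreated and CoQ10 mutants 10, and probucol and CoQ10 mutants 15. Against separate parts of the wild-type livers, these became means of 4.7, 3.95 and 5 over 20 splits. Each part held only some of the 5 wild-type livers, which also lowers the number called. The drop therefore does not show how many calls the shared livers gave. Independent lists would share 0.0142 higher and 0.0543 lower probes for the first pair, 0.00994 and 0.031 for the second and 0.0854 and 0.15 for the third.

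Among the 18 probes that set untreated mutants apart from wild type, Cyp4a12a and Abcc4 were called the other way under the probucol label, and Cyp4a12a and Plekhb1 under the CoQ10 label. The untreated livers enter both comparisons with opposite sign, which by itself favours such opposite calls. Across 15096 probes, which are not independent replicates, the difference of untreated mutants from wild type correlated with the change under treatment at r = -0.24 for probucol and r = -0.34 for CoQ10. Sharing the untreated mutants gives a mean r of -0.49 with no effect at all (1000 simulations), and the covariances of -0.0105 and -0.0177 lay above the simulated -0.0202. With the untreated mutants split between the comparisons the mean r was 0.14 and 0.011. No reversal across probes beyond the shared livers was detected.

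**Figure D3:**
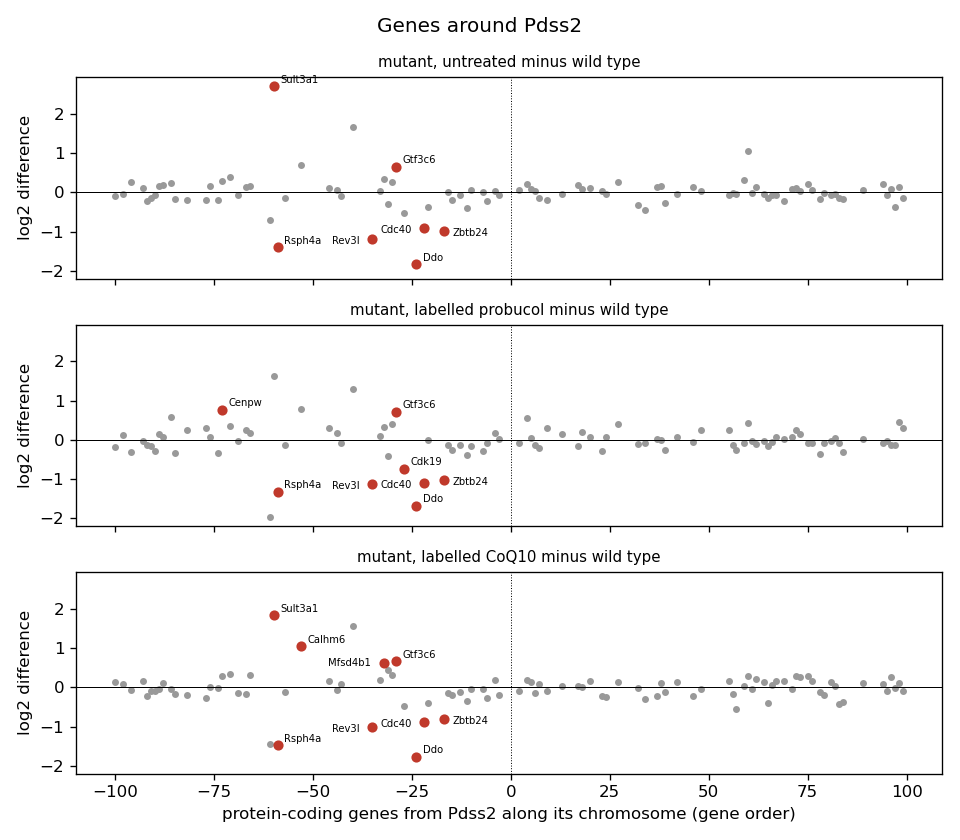
Log2 difference from wild type of the 100 genes measured within 100 protein-coding genes on each side of Pdss2, in the gene order of GRCm38.p6, for each mutant group. Called genes are the large red points, and grey points were not called. Ddo, Rsph4a, Rev3l, Cdc40, Zbtb24 and Gtf3c6 are called in all 3 groups.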

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

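The tests of outlying mice were planned. Among 271 groups of 5 values, 20 held a mouse whose gap to its nearest neighbour exceeded the 95% limit of Dixon's ratio (gap over range), where chance gives about 13.6. In the labels, wild-type replicate 3 had a nephritis score of 1 against 0 in the other wild-type mice (ratio 1), and probucol replicate 3 was 140 days old against 144 to 145 (ratio 0.8). With the other scores tied, any single different score gives a ratio of 1, so the score's flag, counted among the 20, carries no weight.

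Among genes, livers of wild-type mice stood apart for Csrnp1 in replicate 3 (ratio 0.912, higher), Pdk4 in replicate 3 (0.82, lower), H2ac7 in replicate 4 (0.778, lower) and Serpina1e in replicate 2 (0.762, lower). Livers labelled probucol stood apart for Mcm4 in replicate 2 (0.82, higher), Pde6c (0.749) and Gtf3c6 (0.732) in replicate 4, both higher, C1qc in replicate 5 (0.749, lower), Ppargc1a in replicate 3 (0.73, lower) and Akr1b8 in replicate 1 (0.716, lower). Livers labelled CoQ10 stood apart for Ndufa2 (0.892) and Ppargc1a (0.815) in replicate 5, both lower, Krt23 (0.866, lower) and Cox7b (0.772, higher) in replicate 3, G0s2 in replicate 2 (0.759, higher), and Rsph4a (0.734, higher) and Chac1 (0.714, lower) in replicate 4. Among untreated mutants Rsph4a stood apart in replicate 5 (0.735, higher). Rsph4a was not detected in either of those mutant groups.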

How the results depend on the processing

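No called list or named gene changed its direction under the alternatives run on it that were chosen beforehand. Groups by array name prefix were run for counts of probes alone, and they turn every direction between probucol and untreated mutants by construction. The order of comparisons here is untreated mutants against wild type (18 probes), probucol against untreated (2), CoQ10 against untreated (18), probucol against wild type (106), CoQ10 against wild type (66) and probucol against CoQ10 (7). Leaving out 1 mouse gave 14 to 22, 1 to 7, 11 to 37, 24 to 269, 22 to 101 and 2 to 65 probes. Median scaling gave 9, 1, 7, 9, 9 and 2, and 8 of the first 18 probes were still called. A fit of 2 groups alone gave 31, 0, 10, 67, 186 and 0. Other alternatives moved some counts over 1.5 times. For untreated mutants against wild type, array weights gave 47. For probucol against untreated, detection in all 20 arrays and the array number as a block gave 1. For CoQ10 against untreated, no filter gave 11, detection in all 20 arrays 9, a variance trend 31 and array weights 117. For probucol against wild type, no filter gave 55 and array weights 256. For CoQ10 against wild type, no background correction gave 130, no filter 33, detection in all 20 arrays 129, a trend 116, array weights 470 and the array number as a block 317. For probucol against CoQ10, no background correction gave 13, no filter 1, detection in all 20 arrays 19 and a trend 25. The authors' log2 values gave counts within 1.5 times in all 6, but lost calls of named genes that the report gives with each comparison. Groups by array name prefix gave 106, 2, 7, 18, 66 and 18. Without the 2 youngest untreated mutants probucol against untreated gave 5 probes and 3 lists (from 7). The cause was not tested. After seeing the data, livers that stood apart were left out. For probucol they stood apart in genes such as Apcs and Cxcl1, whose differences were then bound to shrink. Without untreated replicates 1 and 4 the first 3 comparisons gave 13, 1 and 60 probes. Without probucol replicates 1, 2 and 4, which leaves 2 livers, probucol gave 0 probes and 1 list against untreated, 13 probes and 4 lists against wild type and 0 probes and 4 lists against CoQ10. List medians then turned to 0.0361 for fatty acid oxidation, -0.0502 for chaperones and -0.19 for cell cycle against untreated, to -0.12 for chaperones and -0.0868 for cell cycle against wild type and to 0.0073 for fatty acid oxidation against CoQ10, none called.

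Deviations of mice with the same replicate number correlated at a mean of 0.129, against -0.0311 for different numbers, but down to -0.32, and 3 of 20 mice correlated best with their own number, so the numbers were not taken to pair mice. The replicate block gave 22, 2, 19, 123, 90 and 15 probes. It lost the calls of Ppargc1a and Mast3 for CoQ10 against untreated (adjusted p = 0.0683 each), Calhm6 for CoQ10 against wild type (0.0567), fatty acid and triglyceride synthesis for untreated mutants (0.0516) and fatty acid oxidation for probucol against CoQ10 (0.0723).

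With an estimated correlation the called lists became 1, 0, 0, 0, 0 and 0 (from 8, 7, 4, 13, 10 and 8). Leaving out CoQ10 replicate 3 gave 9 lists for CoQ10 against untreated, and leaving out 1 mouse gave at least 3. The correlation of genotype and treatment differences was -0.75 for probucol and -0.78 for CoQ10 over called probes alone, which were chosen on the untreated livers. It turned to 0.14 and 0.011 with untreated livers split, where the shared livers no longer force a negative value, and was -0.52 for probucol without the 2 youngest. The nephritis score of probucol against untreated mutants differed by -2.55 without probucol replicate 1 (exact permutation, adjusted p = 0.0238), and by -2.55 to -1.7 over all mice left out. Albumin kept its calls on a log10 scale. Signal over background limits dim probes: Ddo, Rsph4a, Rev3l and Cyp4a12a have only bounds in the groups where they were not detected.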

Other observations

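The tests of gene order, of the clock genes against collection time and array number, and of the array number and the paralogs for male-biased genes were chosen after the results were seen, and what would count for a strain variant was changed once its value was known. The splits of the mice and the test of Y-linked genes were chosen before. Lists not called against wild type in untreated mutants included cholesterol synthesis, where 17 of 18 genes lay higher (median 0.13, camera adjusted p = 0.0605), and female-biased liver genes, where 10 of 14 lay lower (median -0.45, adjusted p = 0.0605) while the 1 member called over all probes, Sult3a1, was higher (2.70 ± 0.40). Sult3a1 is also among the genes called near Pdss2, described next. CoQ biosynthesis genes differed by a median of 0.03 (10 genes, adjusted p = 0.451). The stellate cell and matrix markers lay lower in 9 of 11 genes in livers labelled probucol than in those labelled CoQ10 (median -0.26, adjusted p = 0.00338, and adjusted p = 0.109 with an estimated correlation).

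Genes called between mutant and wild-type livers clustered in a stretch before Pdss2 in the gene order. Of the 15 genes called in untreated mutants, 46.7% lay within 100 protein-coding genes of Pdss2, as did 1.08% of the 9249 genes tested (Fisher's exact test, adjusted p = 5.02e-10). In the 3 mutant groups the share of called genes was at least 8.81 times that of tested genes, which age alone does not predict. All called genes of this window lay before Pdss2, from position -73 (Cenpw) to -17 (Zbtb24), counted in genes. No gene measured from position -16 (Mical1) to 99 (Ddx50), those next to Pdss2 included, was called in any mutant group. A chromosome segment carried along with the mutation, in mice of the 13th backcross generation, is a candidate explanation. In all 3 mutant groups 6 genes of the window were called in the same direction. Such a segment would include the genes nearest Pdss2, none of which was called, so this explanation stays open. That 0 window genes were called between mutant groups says little, as those comparisons called only 2, 12 and 5 genes. A strain variant under a probe could lower signals such as that of Ddo. Of 10 values of other probes of window genes called lower, 9 of them of Ddo over the 3 comparisons, 6 did not move the same way. They repeat the same few probes (Ddo kept 4 and Cdk19 2) against the same wild-type livers, so they are not independent. Rsph4a, Rev3l, Cdc40 and Zbtb24 kept 1 probe each, so a variant could not be examined there. A variant that lowers a signal would not account for the 1 gene called higher in all 3 groups, Gtf3c6. Probe sequences were not examined, so a variant that raises the signal of mutants stays open. The other probe of Gtf3c6 differed by 0.0043, 0.03 and -0.20, so an effect of the probe stays open for that gene.

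In livers labelled CoQ10 the clock activators Arntl, Npas2 and Clock averaged 0.631 ± 0.14 higher than in untreated mutants (log2, SE between livers), carried mostly by Arntl (1.45, against 0.27 for Npas2 and 0.17 for Clock), and Nr1d1, Nr1d2, Dbp, Tef, Per2 and Ciart averaged a difference of -1.66 ± 0.33. The averages were 0.38 ± 0.10 and -1.29 ± 0.29 against wild type, and 0.30 ± 0.19 and -1.08 ± 0.29 against livers labelled probucol, where the activators lay within 2 SE of 0. The 6 genes lay lower within 4 of 4 array numbers, which argues against the array number. A different time of day at collection may account for the opposite directions, but the labels give no time. The CoQ10 diet, the age of that group and such a difference coincide and cannot be told apart.

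Male-biased genes lay higher in livers labelled untreated than in wild type, with Cyp4a12a detected in 5 of 5. No Y-linked probe in these livers exceeded the highest wild-type liver by more than 0.427 on the log2 scale. None was detected in any group and no male liver was measured, so these probes were not shown to report males. Xist, a transcript of female cells, was detected in 5 of 5 of these livers at its brighter probes. It lay at 10.03 to 10.79 and 10.19 to 10.78 (wild type 10.32 to 10.74 and 10.55 to 10.92). Its dimmer probes were detected in 4 of 5. These Xist values argue against male mice among them. The median of the male-biased list was 0.51 with the array number as a block, so the array number does not account for the whole. Over the 7 genes left without the Cyp4a12, Mup and Serpina1 families it was 0.71, the value of C6. Dropping Mup genes near 0 (Mup2 -0.02, Mup3 0.0015) itself raises a median, and no list test was run on the 7. Cyp2d9 (1.41), Hsd3b5 (1.27), Nudt7 (0.97) and C6 lay higher outside those families, none called over all probes at these probes. How much those paralogs account for stays open. Of those 7 genes Elovl3 (-0.18), Gstp2 (-0.31) and Selenbp2 (-0.0096) did not lie higher, the female-biased Sult3a1 did, and the list's call was lost with an estimated correlation (adjusted p = 0.115). Sult3a1 lies in the window near Pdss2 (position -60 in the gene order), so its rise is no clean sign of sex-biased regulation. No biological explanation was tested, and by the array name prefix the pattern would belong to probucol-fed mutants.

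Other splits of the 10 mice of each comparison into 5 and 5 were compared with the real split in 2-group fits, 100 splits each. Untreated mutants against wild type called 31 probes, and 2 of 100 splits, the real one included, called as many (highest other 209). For CoQ10 against untreated mutants the real split called 10 and 3 of 100 called as many (highest other 850). For probucol and CoQ10 against wild type the real splits called 67 and 186, matched by 1 of 100 each, the real one (highest others 9 and 59). For the 2 comparisons of treated mutants with wild type no other split drawn called as many. A share of 1 in 100 is the smallest that 100 splits can give, and the splits ignore the array number, so chance is not excluded. For the 2 before them fewer than 1 in 20 splits called as many, but the splits ignore the array number, and some called far more than the real one, so they do not separate chance from that structure. For probucol against untreated mutants and against CoQ10 the real splits called 0, which all 100 splits reach whatever the data (highest others 212 and 757), so the splits say nothing about chance there. The splits of highest number were uneven in array number in some cases. In that of 757, array numbers 1 and 2 were carried by 4 of 5 mice on one side and 0 on the other, in that of 850 by 4 and 1, in that of 209 by 5 and 1, but in that of 212 by 2 and 3. With the array number as a block, the real comparisons called 25, 1, 14, 116, 317 and 7 probes in the order of the report.

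For gene lists at the preset correlation, the real splits called 10, 7, 6, 13, 11 and 8 lists in the same order, and 9, 32, 34, 2, 9 and 18 of 100 splits called as many. The highest others were 13, 14, 13, 16, 14 and 12. Between livers labelled probucol and wild type fewer than 1 in 20 splits called as many, but these splits too ignore the array number, another called 16, and all of the 13 lists were lost with an estimated correlation (smallest adjusted p = 0.253), so chance is not separated from that structure. Chance cannot be excluded for the other 5 comparisons.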
